A study of Mus musculus with 40 samples.

How the data were processed

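Total RNA from lung pieces of 40 female C57BL/6 mice was measured on two-colour Agilent mouse expression arrays, 1 animal per array. The animals had received a single intratracheal instillation of 0, 18, 54 or 162 µg of TiO2 nanoparticles and were sampled on day 1 or day 28, which gave 8 groups with 5 arrays in each. The lung sample was labelled with Cy5 on every array and a universal mouse reference RNA with Cy3, so that the dyes were never exchanged.

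The deposited scanner files, written by Agilent Feature Extraction 11.0.1.1 per the file headers, hold the median pixel intensity of every spot and of its local background in both channels, without normalization. The same deposited files hold processed signals, an intensity from which the program subtracted the background and which it normalized between dyes within the array. The authors also deposited a matrix of log2 ratios of the Cy5 sample over the Cy3 reference, with no method stated. Each of its 40 columns fitted its own sample's scanner ratios best, with r from 0.981 to 0.996 and slopes from 0.924 to 0.968 over 12316 probes with a Cy5 signal above 500, and the column medians lay between -0.0391 and -0.0149.

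The groups came from the labels. For replicates 1 and 5 of the 162 µg group at day 28, the titles name day 1 and the time entry names day 28. They were placed by the time entry, and alternatives left them out or placed them at day 1. The arrays lay on 5 slides of 8 arrays with 1 array of each group per slide, scanned on 3 days. The slide was entered as a replicate block in an alternative only: deviations from the group means had a median r of 0.104 between arrays of 1 slide and -0.0344 between arrays of different slides, with a range of -0.597 to 0.744 on the same slide.

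The median Cy5 signal per array was 88 to 121.5 over a median background of 66 to 75, and the median Cy3 signal 50 to 68 over 24 to 38. Between 26108 and 33420 probes per array were well above background in Cy5, no probe was saturated, and the number of animals limits the precision. Median signals were background-corrected with normexp at an offset of 50 and normalized within arrays by loess in limma 3.58.1 under R 4.3.3, with the data.table package, version 1.17.8, for reading. The files hold median signals where mean signals had been foreseen. On control replicate 3 of day 1, 69 spots had a local background above 3 times the array median and were left out. With them the fitted background of that array lay far from those of the other arrays, so this choice was made after seeing the data and the fit with all spots is an alternative.

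Of 55681 probes, 28026 were matched to 1 gene symbol through their transcript identifiers with the GRCm38.p6 annotation and 27655 to none. Probes were kept when the Cy5 signal was well above background on at least 4 of the 5 arrays of at least 1 group, which left 30792 probes. Each gene was measured by its probe with the highest mean Cy5 signal (3906 genes had several passing probes), and 15106 of the 21154 genes with a probe were tested.

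One limma model of the 8 groups was fitted to all 40 arrays. Each dose was compared with the 0 µg animals of the same day, so that the 3 comparisons of a day share their controls. A linear trend over the 4 dose levels, the difference of each response between days, and the control animals of the 2 days were tested in the same model. The 162 and 54 µg animals of day 1 were compared as well, a comparison added after seeing the data. Tests were two-sided, and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are given as log2 with the standard error (SE) of the model, and group levels as mean ± SD of the log2 ratio to the reference. The SE and p rest on a spread per gene shared by all 8 groups, not on the spread of the groups compared alone. On simulated data made from these arrays, 55.2% to 70.2% of genes changed by 1.5-fold were called in a comparison and 89.6% to 98.5% of those changed by 2-fold, with 3 to 14 of 14886 unchanged genes called. The simulated genes vary independently of each other and with the same spread in all groups. Calls that come from structure shared between genes and arrays are therefore not covered.

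The genes named were chosen by a rule written before the data were examined: per comparison, the 10 largest rises and 10 largest falls with the same sign on all 5 slides, up to 4 members of each list with the smallest p, and a fixed set of inflammation and lung genes. Of these, a selection is given. Marker and pathway lists fixed at the same time, skeletal muscle, squamous epithelium and circadian clock among them, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 276 tests (46 lists with at least 5 measured members in 6 comparisons), and again with an estimated correlation. Values per array were compared by exact permutation tests, 32 in all, adjusted together. The smallest p that 5 arrays against 5 can give is 0.00794. These tests did not use the slide, since 5 pairs of arrays by slide can give no exact p under 0.0625. The clock index, defined after seeing the data, is the mean of the centred log2 ratios of 9 genes that peak with the Per genes minus the mean of 3 genes of opposite phase (Arntl, Npas2 and Clock).

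Alternatives covered the background correction, the signals used, scaling between arrays, the filter on dim probes, the probe standing for a gene, the limma settings, array weights, the slide block, the arrays in the model, the placing of the 2 arrays with conflicting labels, and each array left out in turn. Added after seeing the data were a fit with the medians of the skeletal muscle and squamous lists as covariates, and one without the arrays that hold skeletal muscle RNA. Probes with no gene symbol were not used in the comparisons.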

Results

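The series asked how the mouse lung responds to a single instillation of titanium dioxide nanoparticles, as part of work on predicting chronic inflammation from inhaled particles. Lung expression was measured at 0, 18, 54 and 162 µg per animal, 1 day and 28 days after instillation, with 5 animals in each of the 8 groups. The arrays held between 26108 and 33420 probes well above background, and correlations between arrays ranged from 0.753 to 0.990.

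Skeletal muscle genes separated the arrays into 2 sets. Of the 20 day 1 arrays, 9 carried high levels of the 8 skeletal muscle genes measured, which include Acta1 (skeletal actin) and Tnni2 (fast troponin I), and 0 of the 20 day 28 arrays did (Fisher's exact p = 0.00123). Their list medians, as log2 over the median of the 40 arrays, were at least 3.92, against at most 0.397 on all other arrays, and Acta1 was 8.47 higher in the median (log2). These arrays were 4 of 5 controls, 3 of 5 at 18 µg, 1 of 5 at 54 µg and 1 of 5 at 162 µg (Fisher's exact p = 0.226 over the 4 groups). For 0 and 18 µg against 54 and 162 µg Fisher's exact p was 0.0698. The list median at 162 µg was -3.36 relative to the controls (exact permutation p = 0.0317, adjusted 0.0635). On 5 of the 9 the squamous epithelium list was also high, with medians of at least 3.28. The first principal component of all genes held 46.4% of the variance and went with the skeletal muscle list median over the arrays (r = 0.9465). The only day 1 control array without skeletal muscle RNA was replicate 1.

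**Figure D1:**
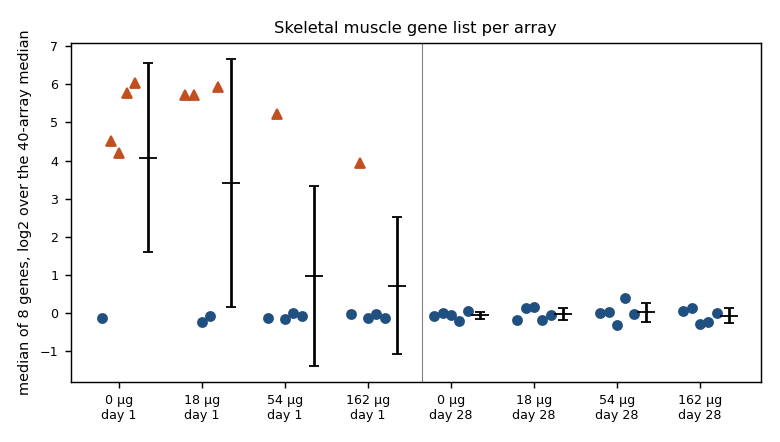
Median of the 8 skeletal muscle genes on each of the 40 arrays (log2 over the 40-array median), by dose and day, with mean and SD of each group. The 9 arrays drawn as triangles, all from day 1, have medians of at least 3.92 and the others of at most 0.397.

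To find what the lowest dose changed after 1 day, the 18 µg animals were compared with the controls. Genes of the circadian clock and its output were among those called. Dbp (D-site binding protein, a clock output regulator) rose by 1.72 ± 0.34 (log2, SE, n = 5 per group; adjusted p = 0.00715), Per2 (a clock repressor, chromosome 1, 91415977 to 91459351) by 1.64 ± 0.25 (adjusted p = 0.000266), and Usp2, a deubiquitinase under clock control, by 1.78 ± 0.31 (adjusted p = 0.00146). Arntl, which encodes the clock activator BMAL1, fell by 1.71 ± 0.27 (adjusted p = 0.00027). Spon2, a secreted matrix protein (chromosome 5, 33213518 to 33218254), fell by 2.44 ± 0.27, or 5.45-fold (adjusted p = 1.22e-06). Usp2, Dbp and Spon2 moved in the same direction on 5 of 5 slides, Per2 and Arntl on 4 of 5.

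Of the 15 clock genes measured, 9 rose, 2 fell and 4 did not pass (11 and 3 adjusted over the list alone). By camera the adjusted p was 1.72e-11, and adjusted p = 0.00256 with an estimated correlation. Per1 rose by 1.52 ± 0.29, Tef by 1.17 ± 0.18, Hlf by 1.13 ± 0.17 and Per3 by 0.97 ± 0.20. The clock index was 1.23 ± 0.31 (SD, n = 5) at 18 µg and -0.64 ± 0.93 in the controls (exact permutation p = 0.00794, adjusted 0.0254). Of 10 glucocorticoid-responsive genes, 3 rose, 0 fell and 7 did not pass (5 adjusted over the list alone). As a group the list had a camera adjusted p of 1.31e-07, and adjusted p = 0.205 with an estimated correlation. The 3 that rose were Zbtb16 (1.62 ± 0.26), Tsc22d3, the glucocorticoid-induced leucine zipper (1.11 ± 0.27), and Per1, which is also in the clock list. Among genes outside these groups, the tetraspanin Tspan4 rose by 1.51 ± 0.25, the mitochondrial carrier Slc25a33 by 1.07 ± 0.14 and the translation regulator Cpeb1 by 0.83 ± 0.11.

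Immune genes were among those that fell. Il18r1, a chain of the interleukin-18 receptor, fell by 1.17 ± 0.26, the interferon-induced tether Bst2 by 0.96 ± 0.21, and the B cell kinase Btk by 0.81 ± 0.16, although a second Btk probe gave only -0.19. The pro-apoptotic genes Bax and Bbc3 fell by 1.00 ± 0.23 and 0.52 ± 0.12, the stress gene Nupr1 by 0.81 ± 0.16, the small GTPase gene Rasl11a by 0.78 ± 0.16, Nxph3 by 0.81 ± 0.12 and the matrix protease Mmp14 by 0.54 ± 0.14. The list medians were -0.28 for 13 monocyte and interstitial macrophage genes (camera adjusted p = 0.000454, adjusted p = 0.276 with an estimated correlation) and -0.29 for 11 B cell genes (0.00499, adjusted p = 0.734 with an estimated correlation). They were -0.32 for 12 ciliated cell genes (0.00666, adjusted p = 0.894 with an estimated correlation) and -0.17 for 14 neutrophil genes (0.0327, adjusted p = 0.584 with an estimated correlation). No member of these 4 lists passed over all genes, and 2, 0, 0 and 2 fell adjusted over the list alone. Of 15 NF-kB targets only Bcl3 fell (-0.52 ± 0.11), and 2 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.0173, adjusted p = 0.471 with an estimated correlation). The acute phase genes Saa3 (-0.60 ± 0.55, adjusted p = 0.824) and Lcn2 (0.06 ± 0.24, adjusted p = 0.973) and the neutrophil gene S100a8 (-0.99 ± 0.32, adjusted p = 0.187) did not pass.

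In total 69 genes rose and 62 fell at 18 µg on day 1. An unadjusted p under 0.05 was found for 1370 genes, where 755 would be by chance. With slide as a block the counts were 96 and 106, and with muscle and squamous levels as covariates 225 and 243, 468 in total. Without the arrays that hold skeletal muscle RNA, which leaves 1 control, 0 genes were called, and without control replicate 3 or 4 the total was 70 or 69. Of the 24 named genes called, 6 lost the call without some single array (Bax, Bbc3, Bst2, Il18r1, Mmp14 and Tsc22d3), with adjusted p up to 0.177 for Mmp14 without control replicate 5. With only the compared groups in the fit 0 genes were called, and with Cy5 alone 55.

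**Figure D2:**
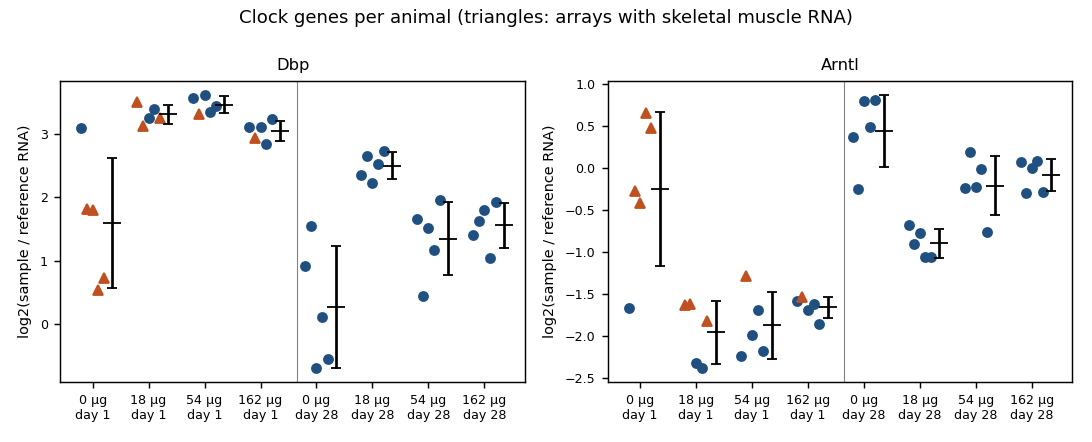
Log2 ratio to the reference RNA of Dbp and Arntl on each array, by dose and day, with mean and SD of each group (n = 5) and triangles for arrays with skeletal muscle RNA. On day 1 Arntl is at -1.67 in control replicate 1 and between -0.42 and 0.66 in the other control animals, and Dbp at 3.09 and between 0.54 and 1.82.

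The comparison of the 54 µg animals with the controls on day 1 asked the same of the middle dose, and it gave the most called genes. Spon2 fell by 2.38 ± 0.27 (adjusted p = 2.35e-06) and Arntl by 1.63 ± 0.27 (adjusted p = 0.000591), while Dbp rose by 1.87 ± 0.34 (adjusted p = 0.00202) and Tspan4 by 1.84 ± 0.25 (adjusted p = 8.15e-05), each on 5 of 5 slides. Among collagen genes Col3a1 (chromosome 1, 45311538 to 45349706) fell by 1.07 ± 0.17, or 2.09-fold, Col1a1 by 0.84 ± 0.15, Col5a1 by 0.60 ± 0.10, Col1a2 by 0.42 ± 0.10 and Col5a3 by 1.31 ± 0.31. Lcn2 (lipocalin-2, an iron-binding acute phase protein) rose by 0.85 ± 0.24 (adjusted p = 0.0348), whereas Saa3 did not pass (0.45 ± 0.55, adjusted p = 0.668).

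Of the 15 clock genes 8 rose, 2 fell and 5 did not pass (10 and 3 adjusted over the list alone). By camera the adjusted p was 1.53e-05, and adjusted p = 0.0861 with an estimated correlation. Per2 rose by 1.44 ± 0.25, Per1 by 1.35 ± 0.29, Tef by 1.16 ± 0.18, and Ciart by 0.84 ± 0.13, while Clock fell by 0.65 ± 0.09. Per3 and Hlf rose 2.15-fold and 2.14-fold. The clock index was 1.26 ± 0.26 (SD, n = 5; exact permutation p = 0.00794, adjusted 0.0254). Of the 10 glucocorticoid-responsive genes 3 rose and 7 did not pass (5 rose and 1 fell adjusted over the list alone). The median of 0.49 had a camera adjusted p of 0.0323, and adjusted p = 0.764 with an estimated correlation. Those that rose were Per1, Tsc22d3 (1.18 ± 0.27) and Klf9 (0.48 ± 0.14).

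Of 18 extracellular matrix genes 6 fell, 2 rose and 10 did not pass (7 and 2 adjusted over the list alone). The median of -0.11 had a camera adjusted p of 0.0109, and adjusted p = 0.255 with an estimated correlation. Ccn2, a growth factor of connective tissue, rose (0.86) and was named after its value was seen. Of 24 cell cycle genes 5 fell, 1 rose and 18 did not pass (11 and 1 adjusted over the list alone). The median of -0.22 had a camera adjusted p of 0.00147, and adjusted p = 0.734 with an estimated correlation. The falls included the mitotic genes Birc5 (-0.58 ± 0.16), Ccna2 (-0.55 ± 0.15), Ube2c (-0.50 ± 0.13) and Ccnb2 (-0.37 ± 0.10). The replication gene Mcm2, also named afterwards, rose (0.30), and Mki67 did not pass (-0.48 ± 0.17, adjusted p = 0.0902). Of 13 T cell genes 2 rose, the receptor chain Cd3d (0.66 ± 0.17) and the transcription factor Tcf7 (0.56 ± 0.14), whose other probe gave 0.02, and 11 did not pass (7 rose adjusted over the list alone). The median of 0.42 had a camera adjusted p of 0.000123, and adjusted p = 0.501 with an estimated correlation. Of 10 alveolar type 1 cell genes only Vegfa rose (0.62 ± 0.18; 2 adjusted over the list alone). The median of 0.34 had a camera adjusted p of 0.0322, and adjusted p = 0.919 with an estimated correlation. Complement, monocyte and ciliated cell genes had list medians of -0.30, -0.28 and -0.27 with 0 members called and 0 adjusted over the list alone (camera adjusted p = 0.0078, 0.0129 and 0.0369, adjusted p = 0.524, 0.501 and 0.987 with an estimated correlation).

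Muscle and squamous genes were lower as groups beside these changes. The medians were -2.91 for the 8 skeletal muscle genes (7 fell adjusted over the list alone; camera adjusted p = 0.000344, adjusted p = 0.624 with an estimated correlation) and -2.16 for 5 squamous genes (5; 0.00893, adjusted p = 0.667 with an estimated correlation). They were -0.90 for 8 smooth muscle genes (5; 0.00298, adjusted p = 0.608 with an estimated correlation) and -0.98 for 11 heart muscle genes (0; 0.0195, adjusted p = 0.919 with an estimated correlation). In each, 0 members passed over all genes. The alveolar type 1 median was 0.013 once muscle and squamous levels were covariates. Of 46 lists 13 were called at 54 µg, and 7 with the covariates.

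Other rises were the receptor gene Tlr12 (1.13 ± 0.17), the cilium gene Cys1 (1.24 ± 0.26), the NRF2 target Osgin1 (1.17 ± 0.25), the NF-kB inhibitors Nfkbia (0.73 ± 0.20) and Tnfaip3 (0.52 ± 0.15), the endoplasmic reticulum stress gene Herpud1 (0.67 ± 0.16) and ferritin heavy chain Fth1 (0.29 ± 0.09). Falls included Cyp26b1, which degrades retinoic acid (-1.87 ± 0.55), Gdpd2 (-1.48 ± 0.31), Fabp7 (-1.29 ± 0.25, above background on 1 of 5 dosed arrays), Fxyd2 (-1.18 ± 0.27) and Mmp14 (-0.67 ± 0.14). The CC chemokine Ccl2 did not pass (-0.75 ± 0.24, adjusted p = 0.0657). Per1, Tsc22d3, Nfkbia, Tnfaip3 and Ccnb2 moved in 1 direction on 4 of 5 slides, the other named genes on 5 of 5.

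The 54 µg comparison called 410 genes higher and 244 lower, with 3326 at an unadjusted p under 0.05, and 750 and 424 with slide as a block. With muscle and squamous levels as covariates 58 genes were called, 48 of them among the 654. Spon2 at -2.02, Arntl at -1.09, Col3a1 at -0.74 and Col5a1 at -0.42 kept the call. Col1a1 at -0.65 (adjusted p = 0.0502) and Cd3d at 0.41 (adjusted p = 0.244) lost it. Without the arrays that hold skeletal muscle RNA 0 genes were called. Ccn2 (-0.35), Per1 (-0.10), Tsc22d3 (-0.06) and Nfkbia (-0.10) turned direction there. Single arrays moved the total widely. It was 1835, 394, 143 and 200 without control replicates 1, 3, 4 and 5. It was 171, 1755, 212 and 306 without 54 µg replicates 1, 2, 3 and 4. Of the 40 named genes called, 20 lost the call without some single array, with adjusted p up to 0.17 for Mcm2 without control replicate 5. Among them were Lcn2, Per1, Tsc22d3, Nfkbia, Col5a3, Col1a2, Vegfa, Ccn2 and the 5 cell cycle genes. The total was 0 with only the compared groups in the fit, 4513 with array weights, 1223 with normexp fitted to all spots and 433 with scaling between arrays.

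The 162 µg animals were compared with the controls on day 1 to see the acute response to the highest dose. Acute phase genes rose. Saa3 (serum amyloid A3, chromosome 7, 46711998 to 46719615) stood at 1.60 ± 1.89 against -2.25 ± 0.96 in the controls (log2 ratio, SD, n = 5), a rise of 3.84 ± 0.55, or 14.4-fold (adjusted p = 9.56e-05). This SE rests on the spread shared by all groups. It is also 0.55 on day 28, where Saa3 at 162 µg lay between -3.72 and -2.68. Saa1 rose by 2.28 ± 0.32 (4.85-fold), and Lcn2 (chromosome 2, 32384637 to 32387739) by 2.06 ± 0.24, from 1.75 ± 0.36 to 3.81 ± 0.49 (adjusted p = 4.89e-06). Saa2 was above background on 0 of 5 control arrays and rose as well (adjusted p = 0.002). Timp1, an inhibitor of matrix metalloproteinases, rose by 1.86 ± 0.27, and the Ly6 family genes Ly6i and Ly6f by 1.88 ± 0.27 and 1.79 ± 0.23.

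Of 19 acute phase genes measured, of 25 listed, 7 rose, 0 fell and 12 did not pass (11 rose adjusted over the list alone). The median of 0.85 had a camera adjusted p of 1.1e-13, and adjusted p = 0.0203 with an estimated correlation. The haem scavenger Hpx rose by 1.05 ± 0.17. Among 13 CC chemokines only Ccl17, which attracts T helper cells, rose (1.61 ± 0.33; 6 adjusted over the list alone). The median of 0.41 had a camera adjusted p of 0.000409, and adjusted p = 0.285 with an estimated correlation. Ccl2 (0.23 ± 0.24) and Ccl7 (0.80 ± 0.32) did not pass. Of 20 interferon-stimulated genes Cxcl10 rose (1.12 ± 0.29; 9 adjusted over the list alone). The median of 0.31 had a camera adjusted p of 2.2e-06, and adjusted p = 0.47 with an estimated correlation. Of 15 NF-kB targets 3 rose, Nfkbia (1.05 ± 0.20), Tnfaip3 (0.71 ± 0.15) and Nfkb2 (0.41 ± 0.10), and 12 did not pass (4 rose adjusted over the list alone). As a group the list had a camera adjusted p of 0.00334, and adjusted p = 0.353 with an estimated correlation. The neutrophil attractants Cxcl5 (1.17 ± 0.33, adjusted p = 0.0715) and Cxcl1 (0.59 ± 0.21, adjusted p = 0.149), the cytokine Il1b (0.30 ± 0.27, adjusted p = 0.619) and S100a8 (-0.14 ± 0.32, adjusted p = 0.87) did not pass.

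Clock genes differed at this dose too: 7 rose, 2 fell and 6 did not pass (9 and 3 adjusted over the list alone). By camera the adjusted p was 0.00166, and adjusted p = 0.255 with an estimated correlation. Per1 rose by 1.57 ± 0.29, Dbp by 1.46 ± 0.34, Per2 by 1.30 ± 0.25 and Tef by 0.97 ± 0.18, and Arntl fell by 1.42 ± 0.27. The clock index was 0.93 ± 0.14 (SD, n = 5; exact permutation p = 0.00794, adjusted 0.0254). Of the 10 glucocorticoid-responsive genes Per1 and Tsc22d3 (1.25 ± 0.27) rose (8 adjusted over the list alone). The median of 0.63 had a camera adjusted p of 8.69e-06, and adjusted p = 0.262 with an estimated correlation.

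Further rises were the anion exchanger Slc26a4 (2.12 ± 0.45), the type 1 cell gene Pdpn (0.86 ± 0.21), the lysosomal protease Ctsk (0.71 ± 0.16), Herpud1 (0.68 ± 0.16), and the heat shock gene Dnajb1 (0.55 ± 0.14). The replication helicase genes Mcm2 (0.52 ± 0.09) and Mcm3 (0.40 ± 0.09) and ferritin heavy chain Fth1 (0.38 ± 0.09) rose as well. Falls were Col5a3 (-1.36 ± 0.31), Fxyd2 (-1.22 ± 0.27), Fabp7 (-1.15 ± 0.25, above background on 1 of 5 dosed arrays), Col14a1 (-1.08 ± 0.21), the fibroblast gene Clec3b (-0.89 ± 0.22), Col3a1 (-0.69 ± 0.17) and the microglia and macrophage receptor Gpr34 (-0.63 ± 0.12). With the processed Agilent signals Col14a1 was at -0.19 (adjusted p = 0.77). Col1a1 did not pass (-0.55 ± 0.15, adjusted p = 0.07). Per1, Per2, Tef, Tsc22d3, Arntl, Cxcl10 and Herpud1 moved in 1 direction on 4 of 5 slides, the other named genes on 5 of 5.

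Cell type lists moved beside these genes, in groups with skeletal muscle RNA on 4 of 5 control arrays and 1 of 5 at 162 µg. Among arrays without it the T cell median was 0.08 in control replicate 1 and -0.07 to 0.325 at 162 µg. The alveolar type 1 median was 0.17 there and -0.20 to 0.20 at 162 µg. The moves below were thus not separated from differences in tissue between the groups. The T cell median was 0.32 with 0 members called and 5 rising adjusted over the list alone (camera adjusted p = 0.00182, adjusted p = 0.62 with an estimated correlation), and the alveolar type 1 median 0.29 with Pdpn called (1 adjusted over the list alone; 0.0301, adjusted p = 0.919 with an estimated correlation). Medians were -0.25 for monocyte genes (0 called, 2 fell adjusted over the list alone; 0.00214, adjusted p = 0.387 with an estimated correlation) and -0.25 for fibroblast genes (Clec3b called, 5; 0.0173, adjusted p = 0.158 with an estimated correlation). They were -0.39 for mesothelial genes (0 and 0; 0.0228, adjusted p = 0.47 with an estimated correlation) and -0.50 for eosinophil, mast cell and basophil genes (0 called, 4 fell and 1 rose adjusted over the list alone; 0.0317, adjusted p = 0.58 with an estimated correlation). The skeletal muscle median was -3.16 (0 called, 8 fell adjusted over the list alone; 2.2e-06, adjusted p = 0.461 with an estimated correlation) and the squamous median -1.40, which did not pass (0.0756). Of 17 fatty acid synthesis genes 0 were called, with 0 adjusted over the list alone (median -0.62, 0.0157, adjusted p = 0.764 with an estimated correlation). Of 16 endoplasmic reticulum stress genes Herpud1 rose (4 adjusted over the list alone; median 0.23, 0.00997, adjusted p = 0.461 with an estimated correlation). Of 46 lists 15 were called at 162 µg, and 11 with muscle and squamous levels as covariates.

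At 162 µg on day 1, 107 genes rose and 36 fell, with 2415 at an unadjusted p under 0.05, and 232 and 85 with slide as a block. With muscle and squamous levels as covariates 20 genes were called, 17 of them among the 143. Saa3 (4.51), Saa1 (2.40), Lcn2 (1.71), Timp1 (1.82), Ly6i (1.59), Ly6f (1.49), Saa2, Hpx (0.93), Mcm2 (0.44) and Gpr34 (-0.62) kept the call. Ccl17 (1.28), Nfkbia (0.69), Dbp (1.15), Arntl (-0.87) and Cxcl10 (1.29) lost it. Without the arrays that hold skeletal muscle RNA 1 control was left and 0 genes were called. Saa3 was then at 4.36 and Lcn2 at 1.66, while Dbp (-0.01), Per2 (-0.04) and Tsc22d3 (-0.02) turned direction. With the 2 arrays of conflicting labels placed at day 1, Saa3 was at 2.57 (adjusted p = 0.0779). On these arrays the log2 ratio of Saa3 was -3.07 and -2.68, against -0.42 to 3.71 on the 162 µg arrays of day 1 and -3.72 to -3.32 on the other ones of day 28. Their clock index was -0.89 and -0.36, against 0.83 to 1.17 and -1.07 to -0.63. The total was 1055 without control replicate 1, and 89, 45 and 47 without control replicates 2, 4 and 5. Without 162 µg replicates 1 and 4 it was 72 and 44. Of the 34 named genes called, 17 lost the call without some single array, with adjusted p up to 0.18 for Nfkb2 without control replicate 5. Slc26a4 lost it without 162 µg replicate 4 (adjusted p = 0.067). With only the compared groups in the fit 0 genes were called, Saa3 and Lcn2 among those lost. The total was 1581 with array weights, 329 with normexp fitted to all spots and 90 with scaling between arrays.

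**Figure D3:**
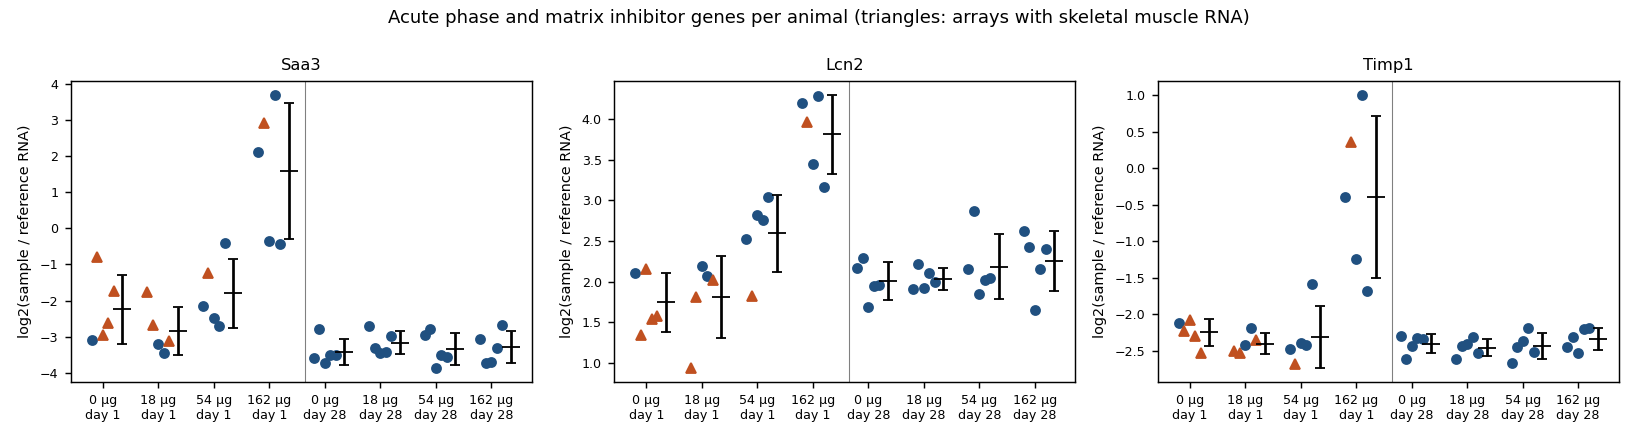
Log2 ratio to the reference RNA of Saa3, Lcn2 and Timp1 on each array, by dose and day, with mean and SD of each group (n = 5) and triangles for arrays with skeletal muscle RNA. On day 1 Lcn2 averages 3.81 at 162 µg and 1.75 in the controls.

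The 162 and 54 µg animals of day 1, which hold 1 array with skeletal muscle RNA each, differed in genes of which some are on the acute phase list. Saa3 was higher at 162 µg by 3.39 ± 0.55 (adjusted p = 0.00206), Saa1 by 2.09 ± 0.32, Slc26a4 by 2.59 ± 0.45, Timp1 by 1.93 ± 0.27, Saa2 by 1.35 ± 0.27 (above background on 2 of 5 arrays at 54 µg), Ly6i by 1.30 ± 0.27, Lcn2 by 1.22 ± 0.24, Ly6f by 1.18 ± 0.23 and Noxo1, an NADPH oxidase organizer, by 1.05 ± 0.17. These were all 9 genes called, with 0 lower and 1262 at an unadjusted p under 0.05 in limma. With only the 2 groups in the fit 0 genes were called, with array weights 433, with the covariates 41, and with slide as a block 20 higher and 8 lower. The acute phase list median per array was 0.70 higher than at 54 µg and 0.90 higher than at 18 µg (exact permutation p = 0.00794, adjusted 0.0254, in both). The neutrophil list median was 0.28 and 0.36 higher (exact permutation p = 0.00794, adjusted 0.0254, in both). The median of the 4 measured CXC chemokines that attract neutrophils was 0.45 higher than at 54 µg (exact permutation p = 0.0159, adjusted 0.0462) and 0.61 higher than at 18 µg (exact permutation p = 0.00794, adjusted 0.0254). Part of these differences lay below the control level. Neutrophil and chemokine means were -0.03 and -0.17 in the controls, 0.13 and 0.23 at 162 µg, -0.15 and -0.22 at 54 µg, and -0.23 and -0.37 at 18 µg. The medians per array were not tested between 162 µg and the controls, a comparison in which the neutrophil list did not pass by camera. Lcn2, Ly6f, Ly6i and Saa2 lost the call without some single array (adjusted p up to 0.24). The total was 5 without 54 µg replicate 1 or 162 µg replicate 1, 15 without 54 µg replicate 5, and 19 and 58 without 162 µg replicates 3 and 5.

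A linear trend over the 4 dose levels was fitted on day 1. Such a slope does not require a rise at every step. Per1 rose by like amounts over the controls at 18, 54 and 162 µg, and Saa3 was not called at 18 or 54 µg. Per dose step Saa3 rose by 1.26 ± 0.17 (adjusted p = 4.51e-05), Saa1 by 0.72 ± 0.10, Lcn2 by 0.70 ± 0.08 (adjusted p = 9.38e-07), Slc26a4 by 0.65 ± 0.14, Ly6i by 0.64 ± 0.08, Ly6f by 0.61 ± 0.07, Timp1 by 0.57 ± 0.08, Ccl17 by 0.52 ± 0.10 and Per1 by 0.45 ± 0.09. The muscle genes Acta1 (-1.86 ± 0.55), Tnni2 (-1.60 ± 0.45) and Tnnc2 (-1.56 ± 0.43) had the largest falls, which were 0.11, 0.04 and -0.01 with muscle and squamous levels as covariates. In total 497 genes rose and 263 fell with dose, with 3619 at an unadjusted p under 0.05. With the covariates 12 genes were called, 11 of them among the 760, and without the arrays with skeletal muscle RNA 0. It was 19 with only the compared groups in the fit, 3975 with array weights, 1304 with slide as a block, 1170 with normexp fitted to all spots, 504 without the filter on dim probes and 417 with scaling between arrays. The total was 2206, 362, 130 and 107 without control replicates 1, 2, 4 and 5, and 1252, 1439 and 464 without 18 µg replicates 3, 4 and 5. It was 494, 1695, 475 and 479 without 54 µg replicates 1 to 4, and 183, 392, 289 and 291 without 162 µg replicates 1, 3, 4 and 5. Acta1, Tnni2 and Tnnc2 lost the call without some single array (Acta1 at adjusted p = 0.137 without control replicate 5).

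**Figure D4:**
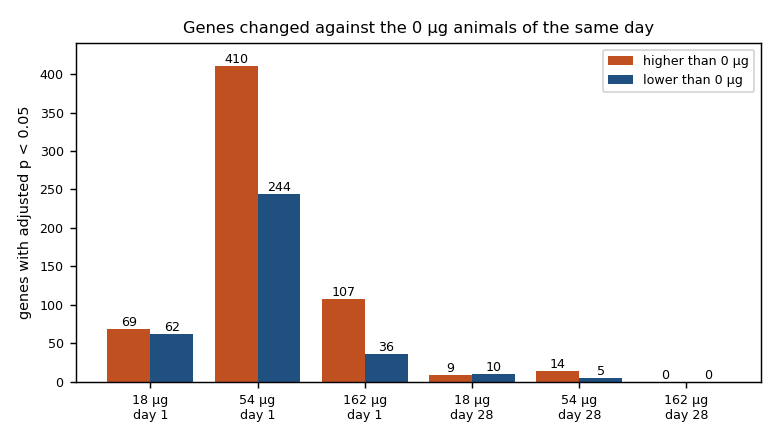
Number of genes with an adjusted p under 0.05, higher and lower than in the 0 µg animals of the same day, by dose and day. On day 1, 54 µg gave 410 higher and 244 lower, and on day 28, 162 µg gave 0.

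To see what remained 28 days after instillation, each dose was compared with the controls of that day, none of whose arrays held skeletal muscle RNA. At 18 µg clock genes again differed. Dbp rose by 2.23 ± 0.34, or 4.71-fold (adjusted p = 0.00125), Per2 by 1.28 ± 0.25, the clock repressors Nr1d1 (REV-ERBα) and Nr1d2 by 1.20 ± 0.19 and 0.88 ± 0.17, Hlf by 0.87 ± 0.17 and Bhlhe40 by 0.72 ± 0.15. Arntl fell by 1.34 ± 0.27 and Npas2 by 0.47 ± 0.09 (above background on 1 of 5 dosed arrays). Cyp26b1 (chromosome 6, 84571414 to 84593908) had the largest fall, -3.20 ± 0.55, or 9.18-fold lower (adjusted p = 0.00502). Spon2 fell by 1.32 ± 0.27 and Rasl11a by 1.03 ± 0.16. Each held on 5 of 5 slides.

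Of the 15 clock genes 5 rose, 2 fell and 8 did not pass (9 and 2 adjusted over the list alone). The median of 0.64 had a camera adjusted p of 4.32e-11, and adjusted p = 0.00256 with an estimated correlation. The clock index was 0.06 ± 0.14 against -1.59 ± 0.53 (SD, n = 5; exact permutation p = 0.00794, adjusted 0.0254). Of the glucocorticoid-responsive genes Zbtb16 rose (1.41 ± 0.26; 5 adjusted over the list alone). The median of 0.41 had a camera adjusted p of 3.9e-06, and adjusted p = 0.255 with an estimated correlation. The 24 cell cycle genes had a median of -0.19 and the 24 sterol synthesis and uptake genes -0.23, with 0 called in both and 4 and 0 falling adjusted over the list alone (camera adjusted p = 1.72e-11 and 5.59e-05, adjusted p = 0.255 and 0.53 with an estimated correlation). Mki67 (-0.54 ± 0.17, adjusted p = 0.317) and Sqle (-0.53 ± 0.24, adjusted p = 0.701) did not pass. With 0 members called, medians were -0.32 for erythroid genes (0.00185, adjusted p = 0.371 with an estimated correlation), -0.20 for monocyte genes (0.032, adjusted p = 0.608), -0.17 for alveolar type 2 genes (0.0477, adjusted p = 0.919) and 0.55 for 6 liver genes (0.00751, adjusted p = 0.47). The 11 heat shock genes had a median of 0.03 and a mean of 0.17 (3 rose adjusted over the list alone; 0.032, adjusted p = 0.53 with an estimated correlation).

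Also called at 18 µg were the kinase genes Map3k6 (0.99 ± 0.22) and Mapk11 (0.52 ± 0.10), both higher. The called genes that were lower were the GTPase gene Rnd1 (-0.84 ± 0.17), Tmem171 (-0.63 ± 0.12), the transcription factor Ikzf4 (-0.51 ± 0.10), Ppp1r11 (-0.25 ± 0.06) and Ncbp3 (-0.72 ± 0.13, with other probes at 0.06 and -0.03). These made up 9 genes higher and 10 lower, with 964 at an unadjusted p under 0.05. With slide as a block 40 genes were called, with the tissue covariates 50, and with the arrays holding skeletal muscle RNA left out of the model 64. With only the compared groups in the fit it was 34 and with array weights 557. Only Cyp26b1, Dbp, Ncbp3, Nr1d1 and Rasl11a kept the call without each single array, the others reaching adjusted p up to 0.222 (Ppp1r11 without control replicate 1). The total was 7, 6 and 6 without control replicates 3, 4 and 5, and 11, 11 and 10 without 18 µg replicates 3, 4 and 5.

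At 54 µg on day 28 Arid5a, an RNA-binding regulator of inflammatory transcripts (chromosome 1, 36307733 to 36324037), rose by 1.30 ± 0.16 (adjusted p = 1.66e-05) and Per1 by 1.83 ± 0.29 (3.57-fold, adjusted p = 0.00182). The stress transcription factor Atf3 rose by 1.34 ± 0.22 (adjusted p = 0.00188), Maff by 0.87 ± 0.18 and the AP-1 gene Fosl2 by 0.85 ± 0.15, with a second Fosl2 probe at 0.15. The integrin gene Itga5 rose by 0.60 ± 0.11, the chaperone gene Dnajb1 by 0.71 ± 0.14, Coq10b by 0.85 ± 0.18, Plekhf1 by 0.58 ± 0.13 and the mevalonate pathway gene Pmvk by 0.57 ± 0.12. The cell cycle inhibitor Cdkn2d fell by 0.32 ± 0.06, the centromere gene Cenpx by 0.32 ± 0.07, the exonuclease gene Exo5 by 0.45 ± 0.10 and Ncbp3 by 0.65 ± 0.13, with other probes at 0.08 and -0.05.

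Per1 was the only 1 of the 10 glucocorticoid-responsive and of the 15 clock genes called (6 and 3 rose, 0 and 1 fell adjusted over the list alone; medians 0.63 and 0.23, camera adjusted p = 1.09e-10 and 0.00319, adjusted p = 0.0828 and 0.276 with an estimated correlation). The clock index was -0.65 ± 0.32 (SD, n = 5; exact permutation p = 0.0238, adjusted 0.0586). The 11 heat shock genes differed by measure: median -0.01, mean 0.18 and a test upward (Dnajb1 called, 3 adjusted over the list alone; camera adjusted p = 0.0327, adjusted p = 0.544 with an estimated correlation), and the median was 0.009 with the deposited ratios. Medians were -0.21 for monocyte, -0.24 for endothelial and -0.18 for complement genes, with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.00326, 0.0323 and 0.0477, adjusted p = 0.432, 0.919 and 0.742 with an estimated correlation).

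In total 14 genes rose and 5 fell at 54 µg on day 28, with 1096 at an unadjusted p under 0.05, 38 with slide as a block, 85 with the tissue covariates and 95 with the arrays holding skeletal muscle RNA left out of the model. It was 39 with only the compared groups in the fit, 230 with array weights, 11 with normexp fitted to all spots and 10 with Cy5 alone. The total was 8, 7 and 8 without control replicates 1, 3 and 5, and 5 and 9 without 54 µg replicates 4 and 5. Arid5a, Atf3, Itga5 and Per1 kept the call without each single array, and the 10 other named genes did not (adjusted p up to 0.188, Plekhf1 without 54 µg replicate 4).

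At 162 µg on day 28 limma called 0 genes, with 998 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0752. The acute phase genes lay near the control level: Saa3 at 0.13 ± 0.55, Lcn2 at 0.24 ± 0.24 and Timp1 at 0.06 ± 0.27. Il1b was at 0.93 ± 0.27 (adjusted p = 0.384, higher on 5 of 5 slides) and Cd3d at 0.45 ± 0.17 (adjusted p = 0.544). The 13 T cell genes had a median of 0.29 (camera adjusted p = 5.67e-06, adjusted p = 0.408 with an estimated correlation), the 10 glucocorticoid-responsive genes 0.32 (5.67e-06, adjusted p = 0.262) and the 15 clock genes 0.21 (0.00234, adjusted p = 0.262), with a clock index of -0.73 ± 0.27 (SD, n = 5; exact permutation p = 0.0238, adjusted 0.0586). Medians were -0.29 for heat shock genes (0.00044, adjusted p = 0.255 with an estimated correlation), -0.15 for endoplasmic reticulum stress genes (0.0317, adjusted p = 0.53) and -0.23 for erythroid genes (0.0301, adjusted p = 0.584). Adjusted over the list alone 4 glucocorticoid-responsive and 2 clock genes rose, 1 clock and 2 endoplasmic reticulum stress genes fell, and 0 of the rest moved. With slide as a block 1 gene was called, with the tissue covariates 16, and with the arrays holding skeletal muscle RNA left out of the model 30. With only the compared groups in the fit 3 were called, with array weights 118, and in the latter 42 genes were called on both days at 162 µg.

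Over the doses of day 28, 6 genes had a rising linear trend and 0 a falling one, with 1048 at an unadjusted p under 0.05 in limma. Per dose step Per1 rose by 0.53 ± 0.09, the immediate early receptor Nr4a1 by 0.48 ± 0.09, the lymphocyte receptor Gpr171 by 0.29 ± 0.05, Arid5a by 0.28 ± 0.05, Fosl2 by 0.24 ± 0.05 and Tob2 by 0.16 ± 0.03 (adjusted p from 0.0185 to 0.0437). Each of the 6 lost the call without some single array (Fosl2 up to 0.244 without control replicate 5). The count was 0 without control replicate 1, 3 or 5 or 162 µg replicate 2 or 5, and 2 without 162 µg replicate 4. It was 25 with only the compared groups in the fit, 110 with array weights, 38 with the tissue covariates, 55 without the arrays with skeletal muscle RNA, and 0 with the 2 arrays of conflicting labels left out.

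Whether a response differed between days was tested directly. At 54 µg Tlr12, an innate immune receptor, had a response lower by 1.34 ± 0.24 (log2 difference -1.34, adjusted p = 0.0454) and Rhebl1, an activator of mTOR signalling, one lower by 0.64 ± 0.12 (-0.64, adjusted p = 0.0459) on day 28. At 18 and 162 µg 0 genes were called. In limma 268, 1146 and 729 genes had an unadjusted p under 0.05 at 18, 54 and 162 µg. Both calls ended without any 1 of 14 arrays (adjusted p up to 0.159). The 54 µg count was 28 without control replicate 1 of day 1 and 6 without 54 µg replicate 2 of day 1, and it was 0 with the tissue covariates or with only the compared groups in the fit. It was 972 with array weights and 9 with slide as a block. Of the lists, the acute phase response at 162 µg was lower on day 28 by a median of -0.73 (camera adjusted p = 6.21e-13, adjusted p = 0.0469 with an estimated correlation). It was the only 1 of 33 differing lists to hold with an estimated correlation. Of the 143 genes called at 162 µg on day 1, 0 were called on day 28 and 127 (88.8%) had the same sign. The log2 folds of the 2 days had r = 0.619 across these genes and 0.317 across all genes, which are not independent replicates. At 162 µg the count was 10, 6, 2, 1, 2 and 1 without 162 µg replicates 3 and 5 of day 1, control replicates 1 and 3 of day 1 and control replicates 3 and 5 of day 28, and at 18 µg it was 1 without control replicate 2 of day 28.

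The control animals of the 2 days were compared to see what changed without particles. Rasl11a was higher on day 28 by 1.11 ± 0.16 (adjusted p = 0.000334), Phlda1 by 0.85 ± 0.17 (adjusted p = 0.0402), the kinase gene Pkn3 by 0.64 ± 0.09 and Ikzf4 by 0.56 ± 0.10, with 0 genes lower and 1668 at an unadjusted p under 0.05 in limma. Phlda1 lost the call without any 1 of 6 arrays (adjusted p up to 0.302, without control replicate 5 of day 1), and the count was 49 and 17 without control replicates 1 and 3 of day 1. It was 0 with only the compared groups in the fit, 1014 with array weights, 23 with normexp fitted to all spots and 12 with Cy5 alone. With the tissue covariates it was 8, of which only 1 was among the 4 genes above. Skeletal muscle RNA was on 4 of 5 control arrays of day 1 and on 0 of 5 of day 28.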

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

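The tests of the explanations for the 3 patterns below were chosen after the results were seen, as were the comparison of 162 with 54 µg and the splits within slides, and the tests for single animals that stand apart, for differences between days, for probes without a gene symbol and for other splits over all arrays were planned.

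The first pattern is the size of the response at 54 µg on day 1, 654 genes, more than at 18 or 162 µg, an order that turned with muscle and squamous levels as covariates, which gave 468, 58 and 20 genes at 18, 54 and 162 µg. One candidate source is muscle and squamous tissue in the lung pieces, since 4 of 5 control arrays but 1 of 5 arrays at 54 µg hold such RNA, and none of the 8 muscle genes is in another list, although 2 are above background on every array without it. The muscle levels of the 18 and 162 µg arrays predict 27.67% of the median rise of the 410 genes called higher (0.13 of 0.46). Another candidate explanation is the time of day at which animals were killed, and no collection times are given. The median difference between 54 and 18 µg was 51.21% of that rise (0.24 of 0.46). This lay between the values foreseen for and against collection time. The 410 genes were chosen for being higher at 54 µg in these same animals, so neither share can decide. Tissue and collection time cannot be told apart from the dose here, because both could differ between these groups, and a response that is largest at the middle dose stays open and was not tested.

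The second pattern is the set of clock genes that differs between dosed and control animals on both days. On day 28 the clock index passed at 18 µg only (exact permutation, adjusted p = 0.0586 at 54 and at 162 µg). On day 1 control replicate 1, the only control without skeletal muscle RNA, had an index of 0.82, near the 0.83 to 1.17 at 162 µg. Without the arrays with such RNA, Dbp and Per2 at 162 µg were at -0.01 and -0.04. Tissue in the lung pieces may add to the day 1 values but is argued against as the whole source, since on day 28, with no muscle RNA on any array, the clock index at 18 µg was 1.65 above the controls (exact permutation p = 0.00794, adjusted 0.0254). A response that grows with the particle dose is argued against by day 28 too, where the index at 162 µg was -0.7877 relative to 18 µg (exact permutation p = 0.00794, adjusted 0.0254). Collection time remains a candidate cause, since all 7 of the clock index genes called at 18 µg on day 28 moved in antiphase as they do over a day, with the Per side up and Arntl and Npas2 down. It cannot be told apart from an effect of instilled particles on the clock that does not grow with dose, because the labels give no collection times.

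The third pattern is the rise of acute phase genes at 162 µg on day 1. Muscle tissue does not account for it, since the list median per array was 0.6988 higher at 162 than at 54 µg (exact permutation p = 0.00794, adjusted 0.0254), groups with 1 array with muscle RNA each, nor does squamous tissue, on 1 array at 162 and 0 at 54 µg, as the list median at 162 µg stayed at 0.7083 with both tissues as covariates (camera adjusted p = 4.29e-23). Collection time is argued against by the list median at 18 µg, -0.0246 against 0.85 at 162 µg, where the clock genes had changed as well. An inflammatory response to the particles may account for it: the list median was 0.9013 higher at 162 than at 18 µg (exact permutation p = 0.00794, adjusted 0.0254) and the neutrophil-attracting CXC chemokines 0.4513 higher than at 54 µg. The chemokine median at 162 µg, 0.23, was however near the 0.20 of the day 28 controls. An inflammatory response remains a hypothesis, as it was found and tested on the same animals. With the 2 arrays of conflicting labels placed at day 1 the Saa3 call ended (2.57, adjusted p = 0.0779), but their values argue against that placing. Saa3 on them, -3.07 and -2.68, lay below the -0.42 to 3.71 of the 162 µg arrays of day 1. Their clock index, -0.89 and -0.36, lay below the 0.83 to 1.17 of those arrays. The slide of each already held a 162 µg array of day 1.

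Other splits of the same arrays were refitted with limma, and the shares are not adjusted over the comparisons. At 18 µg on day 1 the real split called 131 genes, 16 of 100 splits called as many and the highest other called 4164, so chance cannot be excluded. At 54 µg 4 of 100 splits reached 654, the highest other being 4288. Without adjustment over the comparisons that share does not exclude chance. At 162 µg 5 of 100 reached 143, the highest other being 1641, and chance cannot be excluded. The splits with most genes put 5 arrays with skeletal muscle RNA on 1 side and 2, 0 or 0 on the other, which points to a structure of the samples. For the trend of day 1, 3 of 100 splits reached 760 (highest other 1520), an unadjusted share that does not exclude chance either. For 162 against 54 µg 3 of 100 reached 9, which splits within slides did not bear out. The highest other there was 143, with 2 and 0 arrays with muscle RNA, which again points to a structure of the samples.

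On day 28 the real split alone, 1 of 100, gave 19 genes at 18 µg (highest other 7), 19 at 54 µg (highest other 0) and 6 for the trend (highest other 0), and chance can be excluded. At 162 µg limma called 0 genes, with 998 at an unadjusted p under 0.05, which 100 of 100 splits reached (highest other 1). For the difference between days at 54 µg 4 of 100 splits reached 2 genes (highest other 1666, with 0 and 5 day 1 arrays with muscle RNA, a structure of the samples), which splits within slides did not bear out. For the control animals 2 of 100 reached 4 (highest other 17), an unadjusted share that does not exclude chance. Their arrays also differ in skeletal muscle RNA, on 4 of 5 on day 1 and 0 of 5 on day 28. For the differences between days at 18 and 162 µg the count of 0, with 268 and 729 genes at an unadjusted p under 0.05 in limma, was reached by 100 of 100 splits, with highest others of 1425 and 15.

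Those splits moved arrays across slides and left the slide out of the fit. With arrays moved only within slides and the slide as a block, the 16 splits of 2 groups are too few for a share under 0.05. The real and highest other counts were 202 and 841, 1174 and 124, and 317 and 168 at 18, 54 and 162 µg on day 1. They were 40 and 0, 38 and 0, and 1 and 2 on day 28, 6 and 1 for the control animals, and 28 and 51 for 162 against 54 µg. For the trends of day 1 and day 28, 2 of 100 splits reached 1304 (highest other 1414) and 1 of 100 reached 9 (highest other 2). These shares are not adjusted, and chance can be excluded for the day 28 trend alone. For the differences between days at 18 and 54 µg, 14 and 10 of 100 reached 2 and 9 genes (highest others 782 and 391), and chance cannot be excluded. At 162 µg the real count was 0, which any split reaches (100 of 100, highest other 501), so the splits cannot decide there.

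Of 64 groups tested for a single animal apart from the rest, 3 had one, where chance gives about 1 in 20. These were Saa3 in control replicate 2 of day 28 (-2.798, nearest other -3.508), Timp1 in 54 µg replicate 5 of day 1 (-1.58, nearest other -2.389) and Spon2 in control replicate 1 of day 1 (-1.922, nearest other -0.285), all log2 ratios to the reference.

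The response differed between days, as day 28 minus day 1 by an interaction test, for the genes Rhebl1 (-0.6351) and Tlr12 (-1.338) at 54 µg and for 33 lists, 1 of which held with an estimated correlation. The median differences at 18 µg were 0.3988 for B cell, -0.2875 for erythroid, 0.06365 for NF-kB target, -0.113 for sterol, 0.1075 for heat shock, -0.146 for cell cycle, 0.3268 for NK cell, 0.1026 for endoplasmic reticulum stress, 0.05855 for inflammatory cytokine, 0.3401 for smooth muscle and 0.8896 for heart muscle genes. At 54 µg they were -0.2793 for T cell, -0.3228 for alveolar type 1, 0.4119 for ciliated, -0.4101 for endothelial, 1.126 for smooth muscle, 1.237 for heart muscle, 3.272 for skeletal muscle, 2.2 for squamous, 0.2745 for heat shock, 0.1453 for extracellular matrix, -0.4109 for NK cell, 0.1509 for sterol and -0.367 for clock genes. At 162 µg they were 0.1797 for monocyte, -0.2818 for alveolar type 1, 3.196 for skeletal muscle, -0.2495 for CC chemokine, -0.1923 for NF-kB target, -0.3829 for interferon-stimulated, -0.3723 for endoplasmic reticulum stress and -0.1871 for heat shock genes. The list that held was acute phase at 162 µg (-0.73, adjusted p = 0.0469 with an estimated correlation).

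Of 11021 probes without a gene symbol that passed the filter, which no comparison used, 4, 108 and 7 were called at 18, 54 and 162 µg on day 1, 2 and 8 at 18 and 54 µg on day 28, 17 and 1 for the trends of day 1 and day 28, and 1 for the difference between days at 54 µg.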

How the results depend on the processing

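The fit with tissue covariates, the one without arrays holding skeletal muscle RNA, the normexp fit with all spots and the comparison of 162 with 54 µg were chosen after seeing the data, the other alternatives before. Signals near background limit what can be seen, since the median Cy5 signal was 88 to 121.5 over a background of 66 to 75. The cause of the moves below was not tested. Counts are genes called, in the order 18, 54 and 162 µg unless stated. No count here says which genes were called.

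Scaling and signals moved some counts. With the processed Agilent signals the differences between days were 8 at 54 µg and 1 at 162 µg. With the deposited ratios these were 0 and 1, and with no background correction 0 at 54 µg. With scaling between arrays day 1 gave 433 at 54 and 90 at 162 µg, its trend 417 and the 54 µg day difference 5. With Cy5 alone 18 µg on day 1 gave 55 (36 higher, 19 lower, against 69 and 62), 54 µg on day 28 gave 10, the differences between days 1, 1 and 1, the controls 12 and the 162 µg lists of day 28 12. With normexp fitted to all spots day 1 gave 1223 at 54 and 329 at 162 µg and its trend 1170, 54 µg on day 28 gave 11, the 162 µg day difference 1 and the controls 23. Without the filter on dim probes the day 1 trend was 504. With probes above background on all 40 arrays the 54 µg day difference was 5, and with the mean of all probes the 162 µg one was 2. A fold of at least 1.5 left 48, 205 and 71 on day 1, 10 at 54 µg on day 28, and 34 and 0 in the trends.

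The model moved more. With slide as a replicate block day 1 gave 202, 1174 and 317 and its trend 1304, day 28 gave 40, 38 and 1, the day differences at 18 and 54 µg 2 and 9, and 162 against 54 µg 28. With array weights day 1 gave 4513 at 54 and 1581 at 162 µg, day 28 557, 230 and 118, the trends 3975 and 110, the day differences 972 at 54 and 11 at 162 µg, the controls 1014, 162 against 54 µg 433, and 42 genes were called on both days at 162 µg. With only the groups compared in the fit day 1 gave 0, 0 and 0, day 28 34, 39 and 3, the trends 19 and 25, the 54 µg day difference 0, the controls 0 and 162 against 54 µg 0. The fit of 10 arrays has fewer arrays for the spread. On day 28 the counts rose in it, so fewer arrays alone do not account for these moves. The shared spread of the main fit is taken from both days. Skeletal muscle RNA is on 9 of the 20 arrays of day 1 and on 0 of the 20 of day 28. Where the day 1 groups vary more than the shared spread, their p-values in the main fit are too small.

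With muscle and squamous levels as covariates day 1 gave 468, 58 and 20, day 28 50, 85 and 16, the trends 12 and 38, the day differences at 54 and 162 µg 0 and 1, the controls 8, and 162 against 54 µg 41. The trends of Acta1 and Tnni2 turned to 0.1111 and 0.03519. Without the arrays with skeletal muscle RNA, when the lone control of day 1 is assumed to vary like the other groups, day 1 gave 0, 0 and 0 and its trend 0, day 28 64, 95 and 30 and its trend 55, the 54 µg day difference 5, the controls 32 and the 162 µg lists of day 1 7. There Dbp, Per2 and Tsc22d3 at 162 µg turned to -0.01444, -0.04009 and -0.02397, Tsc22d3 at 18 µg to -0.008209, Nfkbia, Per1 and Tsc22d3 at 54 µg to -0.1024, -0.09594 and -0.05984. Ccn2 at 54 µg turned to -0.354, and the day 1 trends of Acta1 and Per1 to 0.01012 and -0.02055.

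With the 2 arrays of conflicting labels left out the day 28 trend was 0 and the day differences 0 at 54 and 4 at 162 µg. Placed at day 1 they left 7 at 18 µg on day 28, a trend of 0, day differences of 1 and 3 and controls of 2. Leaving out single arrays gave 69 to 175, 143 to 1835 and 44 to 1055 on day 1, 6 to 26, 5 to 20 and 0 to 0 on day 28, 107 to 2206 and 0 to 8 in the trends, 0 to 1, 0 to 28 and 0 to 10 for the differences between days, 3 to 49 for the controls, 5 to 58 for 162 against 54 µg, and 14 to 21 and 4 to 10 for the 162 µg lists of day 1 and day 28. Of 2160 values of single genes so obtained 1648 kept their side of the threshold and direction, 502 lost the call, 10 gained it and 0 reversed.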

Other observations

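The values here were looked at after the data were seen, and no hypothesis beyond those weighed above was tested.

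Several groups that lung responses to particles are often read from gave few or no calls at 162 µg on day 1. Of 14 neutrophil genes 0 were called, with a median of 0.02 (camera adjusted p = 0.909). Of 14 NRF2 target genes, which answer oxidative stress, only Fth1 rose (median -0.02, camera adjusted p = 0.928), and Hmox1, which encodes haem oxygenase 1, was at -0.74 ± 0.37 (log2, SE, n = 5 per group; adjusted p = 0.328). Of 8 metallothionein and zinc transporter genes 0 were called, with 3 rising adjusted over the list alone (median 0.09, camera adjusted p = 0.169), and Mt2 was at -0.16 ± 0.45 (adjusted p = 0.894). The 24 sterol synthesis and uptake genes had a median of 0.04 with 0 called (camera adjusted p = 0.758).

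Other macrophage and epithelial groups gave few called genes as well, beside the monocyte list, called lower above, and the alveolar type 1 list, called higher. Among 20 lysosome and phagosome genes only Ctsk rose (median 0.07, camera adjusted p = 0.509), and the macrophage marker Cd68 was at 0.30 ± 0.12 (adjusted p = 0.19, higher on 5 of 5 slides). Of 14 genes of alternatively activated and lipid-handling macrophages 0 were called (median 0.06, camera adjusted p = 0.789), with Arg1 at -0.26 ± 0.49. The surfactant gene Sftpc was at 0.11 ± 0.24, the club cell gene Scgb1a1 at -0.18 ± 0.24 and the type 1 cell gene Ager at 0.18 ± 0.17, none called. The median of 12 genes of the type 2 and mucous response was 0.44 with 0 called (camera adjusted p = 0.491).

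On the 9 arrays with skeletal muscle RNA other lists were high too. The adipocyte list median ranged from 0.95 to 3.80 there and from -1.21 to 1.95 on the other 11 arrays of day 1 (log2 over the 40-array median). The fatty acid synthesis list ranged from 0.16 to 2.60 against -0.27 to 0.39, and the liver list from 0.05 to 1.62 against -0.36 to 0.12. The alveolar type 1 list was lower, from -0.76 to 0.12 against -0.20 to 0.32. High values were not limited to arrays with skeletal muscle RNA. On single arrays of day 28 the adipocyte median reached 4.31, the fatty acid synthesis median 0.784 and the liver median 1.72.

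The clock index of the control animals was -0.64 ± 0.93 (SD, n = 5) on day 1 and -1.59 ± 0.53 on day 28, a difference of -0.95 (exact permutation p = 0.0635, adjusted 0.12). On day 1 it was 0.82 in control replicate 1 and as low as -1.62 in the other controls.

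In 162 µg replicate 3 of day 1 both Xist probes were not well above background, while they were above it on the other 39 arrays. The probes of the Y-linked genes Ddx3y, Uty and Kdm5d were not well above background on that array. The probe of Eif2s3y, also Y-linked, was above background there, and on 36 arrays in all.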
